A study of Mus musculus with 12 samples.

How the data were processed

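Cells were sorted from the aorta and perivascular fat of CD-1 pups at postnatal day 3, of mixed sex, into 4 populations of 3 libraries each, and RNA was amplified with the SMART-Seq v4 Ultra Low Input chemistry, which copies poly(A) RNA, per the labels' protocols. STAR 2.5.2a, DESeq2 1.26.0 and the mm10 genome are named in the submitters' processing notes. The counting tool, its annotation and its use of strand are not given in the sources used here. The authors deposited 3 tables over 36512 genes. The first holds whole-number counts per gene and library as deposited, with no scaling. The second holds a normalized signal which the authors made by dividing counts by 1 factor per library, and these factors equalled DESeq2's median-ratio size factors recomputed from the counts to a relative difference of 8.9e-12. The third, deposited by the authors, holds log2 values, and their correlation across genes with the log2 CPM computed here was at least 0.992 in each library. Tests used the count table.

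Genes were named by their Ensembl identifiers from GENCODE M21 on mm10, which gave a name for 36480 identifiers, and older list symbols were matched through the RefSeq table. Groups were taken from the sample titles. Genes with too few counts were removed with filterByExpr, leaving 21285, which held 99.33% to 99.89% of the counts of each library. Counts were scaled with TMM and tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest) in 1 model over all 12 libraries with a coefficient per population. Contrasts compared the populations in pairs, smooth muscle with the mean of the other 3, and intermediate with the midpoint of progenitor and preadipocyte, and an F test asked for any difference. Tests were two-sided and p-values were adjusted by the Benjamini-Hochberg method, with calls at 0.05. The common biological coefficient of variation was 0.2. Levels are CPM after TMM scaling, except for receptor genes, Lars2, the sums of cell division genes and the limits for a count of 0, which are CPM by library size alone. TMM factors were 0.871 to 0.873 in progenitor, 0.823 to 0.858 in intermediate, 1.07 to 1.19 in preadipocyte and 1.17 to 1.20 in smooth muscle libraries. Fold changes are log2 with the SE implied by the F statistic.

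In total, 33 gene lists were written before the data were examined. Of their 592 entries, 589 were in the table and 564 were tested. Lists were tested with camera (limma 3.58.1) on voom log2 CPM at a preset correlation of 0.01, adjusted over the lists of a comparison. The position of the intermediate libraries was the median over genes of the difference from progenitor divided by the difference between both ends, on log2 CPM with a prior count of 2.

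The genes named were fixed by a rule before the data were examined. In each main comparison these were the 10 with the largest fold change in each direction among genes with an adjusted p under 0.05, a mean log2 CPM of at least 4 and no overlap between the libraries of both sides, without predicted genes. Added to them were up to 4 members with the smallest p from each list described, and Pparg, Pdgfra, Pi16, Dpp4, Ucp1, Myh11 and Acta2 in every comparison. For the midpoint contrast the 5 largest in each direction were taken. Lars2, Gm23935 and the receptor genes were chosen after their values were seen.

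No 2 replicates were the same library: the chi-square per degree of freedom of replicate pairs was 4.06 to 77.2, far above sampling noise, and their correlations of log2 CPM across genes were 0.963 to 0.986. Totals of 11701825 to 17123109 counts put the limit that a count of 0 allows at 0.175 to 0.256 CPM. Intervals of this kind cover counting error only, since reads carry no molecular identifiers.

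The tests were tried on simulated counts over 21285 genes, with each gene's mean over all 12 libraries and the real library sizes and spread. In each comparison 100 genes changed 2-fold and 100 changed 4-fold, up or down. This is far fewer than the genes called in the data, so scaling under such wide differences was not tested. For preadipocyte against progenitor, 42 of 100 genes changed 2-fold and 72 of 100 changed 4-fold were recovered, with 10 false calls among 124. For smooth muscle against the mean of the other 3, 69 and 86 of 100 were recovered, with 12 false calls among 167. A simulated intermediate placed at 0.3 and 0.5 of the way to preadipocyte was measured at 0.312 and 0.495.

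Alternatives were DESeq2-type size factors and library size alone in edgeR, DESeq2 1.42.0, limma-voom with quality weights, no low-count filter, at least 5 CPM in 3 libraries, fits to the compared groups alone, a replicate block, leaving out each library, other minimum folds for the position, camera with an estimated correlation, and fry. Protein-coding genes alone, list counts without preadipocyte replicate 3, and subtraction of an even background were added after seeing the data. The background was the count per kilobase of exon over 1223 olfactory and vomeronasal receptor genes in each library, multiplied by each gene's exon length. Figures were drawn with matplotlib.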

Results

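The series measured poly(A) RNA of cells sorted by flow cytometry from the aorta and its surrounding perivascular fat of CD-1 mouse pups at postnatal day 3. The labels name 4 sorted populations, called here progenitor, intermediate, preadipocyte and smooth muscle, with 3 libraries each. The labels do not give the gates. Libraries held 11701825 to 17123109 counts over 36512 genes, of which 21285 had enough counts to be tested. Totals were 14778738 to 17123109 in progenitor, 12862486 to 15550623 in intermediate, 15148249 to 15739798 in preadipocyte and 11701825 to 13256506 in smooth muscle libraries. Nothing in the labels says that replicates came from separate litters or sorts, so p-values measure the spread between these samples, which may be technical. Of the genes tested, 16988 differed among the 4 populations by edgeR's quasi-likelihood F test at an adjusted p under 0.05.

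Genes chosen beforehand as markers differed among the 4 populations. Because the gates are not given, surface markers among them and in the lists below may have been used in the sort. Their differences would then be set in part by the design. Pi16, a marker of adventitial and adipose progenitors, stood at 839 ± 124 CPM after TMM scaling (SD, n = 3) in progenitor, 101 ± 8.52 in intermediate, 12 ± 4.97 in preadipocyte and 9.96 ± 3.23 in smooth muscle libraries. Pdgfra, a receptor of mesenchymal cells, was at 524 ± 35.9, 303 ± 23.5, 105 ± 23.4 and 34.2 ± 4.99 CPM in the same order of groups. Dpp4 was at 93.2 ± 5.34 CPM in progenitor and 76.6 ± 8.70 in smooth muscle libraries, against 4.25 ± 1.28 in intermediate and 4.0 ± 1.56 in preadipocyte libraries. Pparg, the transcription factor that drives adipocyte differentiation, was at 54.9 ± 3.32, 8.23 ± 1.0, 296 ± 95.3 and 3.72 ± 1.13 CPM in progenitor, intermediate, preadipocyte and smooth muscle libraries. Ucp1, the uncoupling protein of thermogenic fat, was at 119 ± 36.3 CPM in preadipocyte libraries and at 5.36 ± 1.52, 3.09 ± 1.42 and 1.3 ± 0.278 CPM in progenitor, intermediate and smooth muscle libraries. The contractile genes Myh11 and Acta2 were highest in smooth muscle libraries, at 1132 ± 209 and 5335 ± 199 CPM, and next in intermediate libraries, at 112 ± 35.2 and 669 ± 120 CPM. In progenitor libraries they were at 2.10 ± 0.386 and 32.9 ± 7.75 CPM, and in preadipocyte libraries at 16.8 ± 2.66 and 107 ± 32.9 CPM. On mm10, Pparg lies on chromosome 6 from 115360951 to 115490399, Ucp1 on chromosome 8 from 83290352 to 83298452, and Myh11 on chromosome 16 from 14194535 to 14291372. Exons of 89 of the 298 genes named by the rule overlap other annotated genes, among them Pi16, Pdgfra, Dpp4, Hhip, Gli1, Notch3, Tnc, Eln, Fbn1, Mfap4, Enpp2, Itga8 and Penk. With the strand of counting not given in the sources used here, the counts of these genes are uncertain to that extent.

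**Figure D1:**
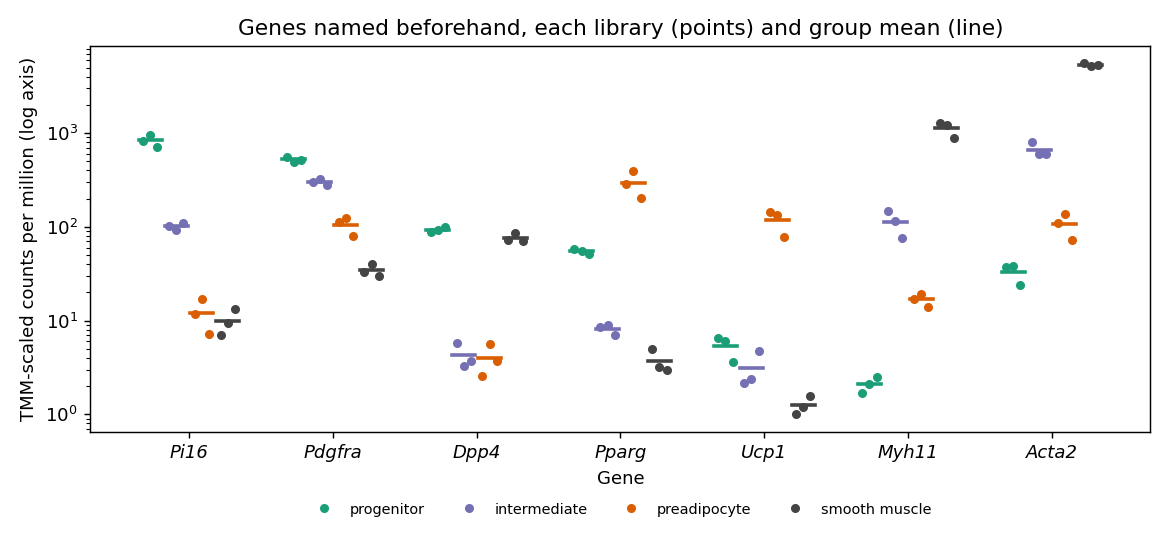
CPM after TMM scaling (log axis) of 7 genes in each of the 12 libraries (points) with the mean of each population (line). Pparg and Ucp1 were highest in preadipocyte libraries, Pi16 and Pdgfra in progenitor libraries, and Myh11 and Acta2 in smooth muscle libraries.

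Several measures of library content moved with the populations. Olfactory and vomeronasal receptor genes are 1223 genes used in sensory neurons. By library size alone they held 926 ± 175 CPM (SD, n = 3) in smooth muscle, 255 ± 109 in intermediate, 112 ± 86.1 in preadipocyte and 71.9 ± 30.1 in progenitor libraries. Of these 1223 genes, 1162 to 1212 had at least 1 count in each smooth muscle library. Smooth muscle libraries also had counts in the most genes, 35363 ± 230, at totals of 11701825 to 13256506 counts that overlap those of intermediate libraries. Haemoglobin genes held 1.84% of counts in preadipocyte replicate 3, against 0.114% and 0.129% in preadipocyte replicates 1 and 2 and at most 0.0253% in the other libraries. Transcripts of the mitochondrial genome took 3.13% ± 0.495 of counts in preadipocyte libraries and 0.694% ± 0.0594 to 1.29% ± 0.102 in the other populations. By library size alone, Lars2 was at 12574 ± 2883 CPM in intermediate, 15173 ± 5502 in smooth muscle and 2650 ± 960 in progenitor libraries. TMM factors were lower in intermediate than in smooth muscle libraries, so the order of these 2 populations can turn with the scaling. Among preadipocyte libraries, Lars2 was at 14218 CPM in replicate 1, 1719 in replicate 2 and 2837 in replicate 3. Gm23935 took 0.615%, 0.0459% and 0.0786% of counts in the same 3 libraries. Its share was 0.461% to 0.717% in intermediate, 0.520% to 0.916% in smooth muscle and 0.0844% to 0.113% in progenitor libraries. Gm23935 thus moved with Lars2, and the source of the counts on both was not tested.

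**Figure D2:**
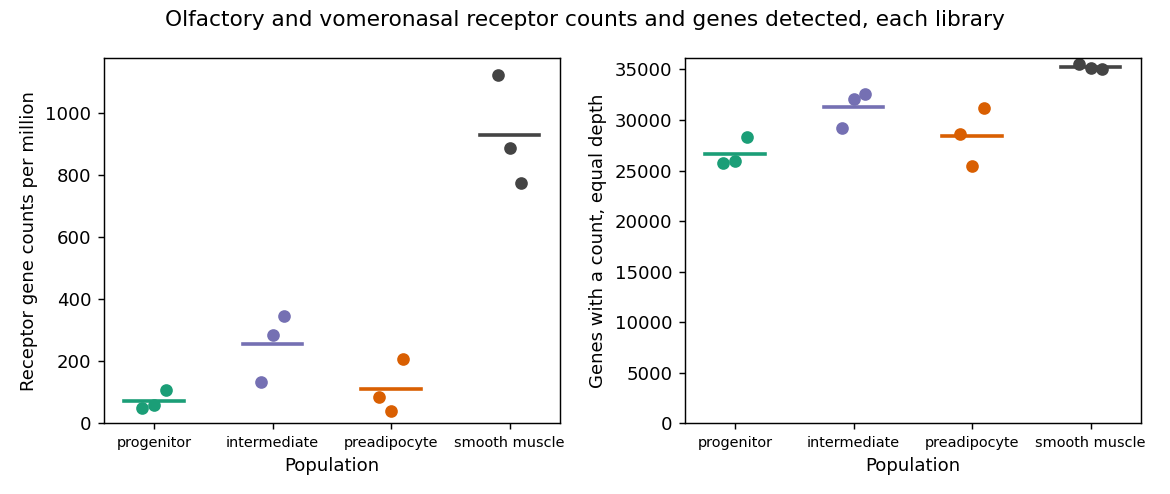
Left, CPM by library size alone in 1223 olfactory and vomeronasal receptor genes, and right, genes with at least 1 count after every library was thinned to 11701825 counts, for each library (points) and as population means (lines). The 3 smooth muscle libraries were above the 9 others in both plots.

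The comparison of preadipocyte with progenitor libraries asks which genes separate the cells labelled preadipocyte from those labelled progenitor. Genes of lipid storage and fat cell secretion were higher in preadipocyte libraries in 29 of 30 tested cases. Fabp4, a fatty acid carrier, was higher by 3.54 ± 0.18 on the log2 scale (SE), from 210 to 2450 CPM, and Cfd, which encodes adipsin, by 6.64 ± 0.38, from 0.601 to 61.7 CPM. Adipoq, the adiponectin gene, rose from 59.6 ± 16.6 to 953 ± 279 CPM and Car3 from 555 ± 123 to 8109 ± 3018 CPM. Genes of the extracellular matrix moved the other way, and all 22 fibroblast genes tested were lower. Col1a2 went from 48440 to 3690 CPM and Col3a1 from 96530 to 9259 CPM. Ly6a, which encodes the progenitor surface marker Sca-1, fell from 748 to 2.62 CPM.

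Brown fat and thermogenic genes were higher in 19 of 24 tested cases and lower in 2. Among them, Ucp1 was higher by 4.48 ± 0.30, Adrb3, the beta-3 adrenergic receptor, by 3.94 ± 0.24, Cox7a1 by 4.61 ± 0.31 and Ppargc1a, a coactivator of mitochondrial gene expression, by 3.83 ± 0.27 on the log2 scale. All 33 oxidative phosphorylation genes tested were higher, with a median of 1.78, and so were 17 of 19 fatty acid oxidation genes, with 1 lower. Examples were Cycs, which encodes cytochrome c, at 133 against 756 CPM, Uqcrfs1 at 110 against 616 CPM, and Acadl at 73.7 against 372 CPM. All 13 mitochondrially encoded genes were higher as well, mt-Nd1 by 1.71 ± 0.13. The camera test gave an adjusted p of 7.25e-16 for adipocyte lipid genes (adjusted p = 0.146 with an estimated correlation), 7.38e-08 for brown fat genes and 1.08e-09 for fatty acid oxidation (each adjusted p = 0.182 with an estimated correlation), 1.95e-21 for oxidative phosphorylation and 1.19e-08 for mitochondrially encoded genes (each adjusted p = 0.137 with an estimated correlation).

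All 28 cell division genes tested were higher in preadipocyte libraries, Birc5 by 2.43 ± 0.17 and Cenpa by 2.11 ± 0.15 (list adjusted p = 2.58e-17). For this list, adjusted p = 0.146 with an estimated correlation. The 9 red blood cell genes tested were higher too, among them Tfrc, the transferrin receptor, by 4.05 ± 0.44, with a list adjusted p of 0.0112 (adjusted p = 0.521 with an estimated correlation). The call of this list ended with library size alone (adjusted p = 0.113) and with any 1 of 6 progenitor or intermediate libraries left out (adjusted p = 0.0537 to 0.081). The haemoglobin genes Hbb-bs and Hba-a1 headed the genes higher in preadipocyte libraries at 2647 ± 3796 and 2830 ± 3932 CPM. Replicate 3 held 7029 and 7370 CPM of them, and each has a near-identical copy that can share its reads. Without preadipocyte replicate 3, a check chosen after seeing the data, 28 of 28 cell division genes and 8 of 9 red blood cell genes were still called higher, and 1 red blood cell gene was lower. The median of the red blood cell list went from 5.19 to 2.71 without it, and Tfrc was at 192.5, 291.7 and 931.8 CPM in preadipocyte replicates 1, 2 and 3. Lipid, thermogenic and oxidative phosphorylation counts were 29, 19 and 33 genes higher without that library.

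Of 22 progenitor markers, 21 were lower in preadipocyte libraries and 1 was higher. Mfap5 changed by -4.52 ± 0.15, Ly6c1 by -7.29 ± 0.26 and Cd248 by -4.06 ± 0.16 as log2 fold changes. Elastic fibre genes were lower in 16 of 16 tested cases, Mfap4 going from 4419 to 290.2 CPM and Fbn1, the fibrillin gene, from 2103 to 179 CPM. Hedgehog pathway genes were lower in 10 of 10 cases. Hhip, a Hedgehog-binding protein, went from 202 ± 18 to 2.29 ± 0.790 CPM, and Gli1, a transcriptional effector of the pathway, from 31.1 to 2.57 CPM. TGF-beta response genes were lower in 18 of 20 cases with Postn at 13080 against 1456 CPM, cytokines and chemokines in 16 of 17 with Il33 at 488 against 40.3 CPM and Il6 at 486 against 43.7 CPM, and IGF pathway genes in 10 of 11 with Igfbp5 at 355 against 20.8 CPM. The camera test called progenitor markers (5.11e-16), fibroblast genes (4.27e-18), elastic fibre genes (4.95e-13), Hedgehog genes (1.99e-07) and cytokines (1.58e-08) by adjusted p. For each of these 5 lists, adjusted p = 0.136 with an estimated correlation. TGF-beta response genes (8.21e-09) and IGF pathway genes (1.08e-06) were called too, and for each adjusted p = 0.137 with an estimated correlation.

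Immediate early and dissociation stress genes, which respond to tissue handling, were lower in preadipocyte libraries in 18 of 20 cases and higher in 1 (adjusted p = 1.58e-08). For this list, adjusted p = 0.182 with an estimated correlation. Dusp1 was at 1872 CPM in progenitor and 479 in preadipocyte libraries, and Atf3 at 1123 and 283 CPM. The list written as committed preadipocyte markers went both ways, with 5 of 16 higher and 9 lower. Fabp4 and Cd36 were higher, and Vcam1, an adhesion molecule, and Gpc3, a surface proteoglycan, changed by -2.19 ± 0.12 and -2.80 ± 0.16. Adipogenic transcription factors also split, with 8 of 19 higher and 5 lower, a median of -0.04 (0.345 with library size alone) and a mean of 0.389, the sign of the test being that of the mean. Pparg was higher by 2.43 ± 0.21 and Srebf1 by 1.72 ± 0.20, while Cebpd changed by -2.34 ± 0.17. Neither list was called as a set (adjusted p = 0.114 and 0.617).

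Markers of other cell types moved in this comparison as well. Schwann and neuronal markers were higher in preadipocyte libraries in 13 of 15 cases and lower in 1, with Dbh at 0.372 against 19.3 CPM and Stmn2 at 0.961 against 35.8 CPM (list adjusted p = 0.000646; adjusted p = 0.182 with an estimated correlation). Mesothelial markers were lower in 10 of 12 cases (0.00224; adjusted p = 0.394 with an estimated correlation) and basement membrane genes in 14 of 19 with 1 higher (0.00019; adjusted p = 0.317 with an estimated correlation). Endothelial markers were higher in 10 of 17 cases and lower in 3, contractile genes higher in 8 of 25 and lower in 7, and pericyte markers higher in 6 of 13 and lower in 6. None of these 3 lists was called (adjusted p = 0.153, 0.845 and 0.607). The pericyte list had a median of 1.02, a mean of -0.178 and a test pointing down.

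In all, 10843 genes differed between preadipocyte and progenitor libraries by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 5340 higher and 5503 lower, and 7048 of them by at least 2-fold. With scaling by library size alone, which moved the median log2 fold change of all genes by 0.389, 7857 were higher and 3773 lower. Adjusted over the list alone, 29 lipid, 19 thermogenic, 33 oxidative phosphorylation and 28 cell division genes were higher and 22 fibroblast, 16 elastic fibre and 10 Hedgehog genes lower, as over all genes tested.

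The comparison of intermediate with progenitor libraries asks which genes set the cells labelled intermediate apart from those labelled progenitor. Contractile genes of smooth muscle were higher in intermediate libraries in 19 of 25 tested cases and lower in 1. Myh11 was higher by 5.73 ± 0.28 on the log2 scale, Acta2 by 4.34 ± 0.25, Actg2 by 4.89 ± 0.32 and Lmod1 by 3.18 ± 0.21. Pericyte markers were higher in 10 of 13 cases, among them Rgs5, a regulator of G protein signalling, from 20.0 ± 2.87 to 337 ± 33.1 CPM, and Notch3 from 29.3 to 227 CPM. Progenitor markers were lower in 22 of 22 cases, which the sort may set in part. Ly6a went from 748 to 1.99 CPM, Ly6c1 from 215 to 1.5 CPM and Bmp7 from 27.3 to 0.738 CPM.

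Notch pathway genes were higher in 9 of 12 cases, with Heyl, a Notch target, at 37.7 ± 5.88 against 360 ± 20.1 CPM and the ligand gene Jag1 at 64.0 against 381 CPM. Basement membrane genes were higher in 11 of 19 cases and lower in 2. The collagen IV genes Col4a5 and Col4a6 were higher by 3.15 ± 0.22 and 4.66 ± 0.24. Matrix genes among the largest increases were Tnc, the tenascin C gene, from 48.3 ± 13.2 to 1210 ± 78.6 CPM and Col11a1 from 35.2 ± 4.12 to 328 ± 7.69 CPM. Elastic fibre genes were higher in 7 of 16 cases and lower in 3, with Eln, the elastin gene, at 4575 against 18270 CPM and Efemp1 lower at 217 against 15.8 CPM. Hedgehog genes were higher in 4 of 10 cases and lower in 2, and the 4 with the smallest p were all higher: Ptch1 by 1.75 ± 0.17, Hhip by 1.58 ± 0.16, Gli1 by 1.31 ± 0.16 and Gli2 by 1.02 ± 0.19.

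Adipocyte lipid genes were lower in 13 of 30 cases and higher in 2, and Pparg changed by -2.73 ± 0.23, Lpl, the lipoprotein lipase gene, by -2.67 ± 0.16 and Adipoq by -2.20 ± 0.27. Oxidative phosphorylation genes were lower in 26 of 33 cases and fatty acid oxidation genes in 10 of 19. Ndufa4 changed by -1.01 ± 0.13 and Pdk4 by -1.46 ± 0.24. Ucp1 did not pass the test at -0.80 ± 0.33 (adjusted p = 0.0805). Cytokines and chemokines were lower in 14 of 17 cases, with Cxcl13 at 76.5 ± 19.3 against 2.85 ± 1.07 CPM and Ccl2 at 745 against 124 CPM. Complement genes were lower in 9 of 12 cases, C4b changing by -3.35 ± 0.21, and interferon response genes in 10 of 16, Ifi27l2a changing by -2.39 ± 0.25. Among single genes, Scara5 went from 766 ± 20.3 to 30.4 ± 1.61 CPM, Enpp2 from 227 ± 23.1 to 8.04 ± 0.595 CPM and Dpp4 from 93.2 to 4.25 CPM.

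By camera, progenitor markers were called at an adjusted p of 3.47e-28, and of the lists called in the 4 main comparisons this was the 1 that was also called with an estimated correlation (adjusted p = 0.0309 with an estimated correlation). Contractile genes (4.02e-13) and Notch genes (1.53e-08) were called with the preset correlation, and for each adjusted p = 0.0942 with an estimated correlation. Pericyte markers were called at 2.66e-09 (adjusted p = 0.0537 with an estimated correlation), cytokines at 1.84e-12 (adjusted p = 0.0759 with an estimated correlation) and complement genes at 8.27e-09 (adjusted p = 0.0805 with an estimated correlation). Oxidative phosphorylation was called at 5.14e-12 (adjusted p = 0.379 with an estimated correlation) and adipocyte lipid genes at 6.91e-05 (adjusted p = 0.52 with an estimated correlation). Interferon response genes were called at 0.000164 (adjusted p = 0.355 with an estimated correlation). Fatty acid oxidation (5.27e-05), basement membrane (0.000217) and Hedgehog genes (0.0121) were called as well, and for each adjusted p = 0.427 with an estimated correlation. Elastic fibre genes were at 0.0354 (adjusted p = 0.569 with an estimated correlation). Adjusted over the list alone, 19 contractile, 12 pericyte and 11 Notch genes were higher and 22 progenitor markers, 16 lipid and 30 oxidative phosphorylation genes lower.

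Markers of 2 other cell types were also higher in intermediate libraries, from low levels. Endothelial markers were higher in 12 of 17 cases and lower in 2, with Ptprb at 2.14 against 35.4 CPM, Flt1 at 5.40 against 28.5 CPM and Tek lower at 117 against 13.9 CPM (list adjusted p = 0.000391; adjusted p = 0.427 with an estimated correlation). Schwann and neuronal markers were higher in 12 of 15 cases and lower in 1, with Stmn2 at 0.961 against 5.44 CPM (list adjusted p = 0.000316; adjusted p = 0.355 with an estimated correlation). Receptor genes, at 71.9 CPM in progenitor and 255 CPM in intermediate libraries, moved the same way. With an even background set from these genes subtracted, a check chosen after seeing the data, 18 contractile, 10 pericyte, 9 Notch, 12 endothelial and 12 Schwann and neuronal genes were higher. In all, 5870 genes differed, 3009 higher and 2861 lower, and 4877 with the background subtracted. With no low-count filter 2354 were higher and 4362 lower. Without intermediate replicate 2 the count was 3577, a change of over 1.5 times.

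The comparison of preadipocyte with intermediate libraries called 8552 genes at 2-fold or more, against 7048 for preadipocyte and 3021 for intermediate against progenitor. Fabp4 was at 59.1 CPM in intermediate and 2450 CPM in preadipocyte libraries, Adipoq at 13.0 ± 1.5 and 953 ± 279 CPM, and Pparg at 8.23 and 296 CPM. Lipid genes were higher in preadipocyte libraries in 27 of 30 cases and lower in 1, brown fat and thermogenic genes in 21 of 24 and lower in 3, and oxidative phosphorylation genes in 33 of 33. Hhip went the other way, from 604 ± 26.3 to 2.29 ± 0.790 CPM, as did Epha3, an ephrin receptor gene, which changed by -6.55 ± 0.18 and Ntn1, the netrin 1 gene, by -5.38 ± 0.16 on the log2 scale. Hedgehog genes were lower in 10 of 10 cases, elastic fibre genes in 14 of 16 with 1 higher, contractile genes in 19 of 25 with 2 higher, and pericyte markers in 9 of 13 with 1 higher. Immediate early and dissociation stress genes were lower in 16 of 20 cases and higher in 1.

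Among thermogenic genes, Ucp1 was higher by 5.28 ± 0.33, Cox7a1 by 5.77 ± 0.34 and Ppargc1b by 4.52 ± 0.30. G0s2 and Gpd1, genes of triglyceride metabolism, were higher by 5.30 ± 0.23 and 6.17 ± 0.36. All 28 cell division genes were higher, Rrm2 by 2.93 ± 0.23, and 9 of 9 red blood cell genes, Hba-a1 by 9.80 ± 1.25, with haemoglobin concentrated in preadipocyte replicate 3 as given above. Fibroblast genes were lower in 20 of 22 cases and higher in 1, with Col1a2 at 67870 against 3690 CPM. Basement membrane genes were lower in 16 of 19 cases and higher in 2, Col4a6 changing by -5.67 ± 0.26, and Notch genes in 7 of 12 with 1 higher, Heyl changing by -4.69 ± 0.21. Tnc changed by -5.36 ± 0.30 and Rgs5 by -5.12 ± 0.20. Dpp4 was at 4.25 and 4.0 CPM and did not pass the test (-0.09 ± 0.26; adjusted p = 0.792), and its sign changed with the scaling.

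The camera test called lipid genes (adjusted p = 2.41e-15), thermogenic genes (6.22e-08), oxidative phosphorylation (3.82e-24), cell division (1.28e-14), fibroblast (2.95e-11), elastic fibre (3.99e-10), Hedgehog (7.41e-07) and pericyte genes (0.000659). For each of these 8 lists, adjusted p = 0.232 with an estimated correlation. It also called contractile genes at 5.12e-06 (adjusted p = 0.254 with an estimated correlation), basement membrane genes at 2.72e-06 (adjusted p = 0.262 with an estimated correlation), Notch genes at 0.0061 (adjusted p = 0.325 with an estimated correlation) and red blood cell genes at 0.0107 (adjusted p = 0.585 with an estimated correlation). The call of red blood cell genes ended with library size alone (adjusted p = 0.148) and without intermediate replicate 1 or 3 (adjusted p = 0.0557 and 0.0629). Adjusted over the list alone, 27 lipid, 21 thermogenic and 33 oxidative phosphorylation genes were higher and 10 Hedgehog, 14 elastic fibre and 20 contractile genes lower. In all, 12157 genes differed, 5540 higher and 6617 lower, with a median log2 fold change over all genes of -0.244. With library size alone this median moved by 0.432, and 7760 genes were higher and 4233 lower.

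The label intermediate poses the question of whether these cells lie between progenitor and preadipocyte. Over the 7048 genes that differed by at least 2-fold between those populations, the intermediate libraries lay at 0.0298 ± 0.0052 (SD, n = 3) of the way from progenitor (0) to preadipocyte (1). With library size alone this position was -0.00146, with a minimum of 5 CPM in 3 libraries -0.0380, with no low-count filter 0.0959 and over genes that differed at least 4-fold 0.147. A simulated population with progenitor levels came out at 0.0295 ± 0.0013 in the same calculation. Of these genes, 46.5% lay between the other populations in the intermediate mean, 46.9% lay below 0 and 6.63% above 1. Genes at progenitor levels would also scatter to both sides of 0, so the share between does not by itself show an intermediate position. Against the midpoint of progenitor and preadipocyte, 10613 genes differed, 6043 higher and 4570 lower, by edgeR. With library size alone, which moved the median of all genes from 0.164 to -0.0738, 4240 were higher and 6404 lower. Tnc was above the midpoint by 5.0 ± 0.22 on the log2 scale, Hhip by 4.81 ± 0.14, Rgs5 by 4.60 ± 0.15, Epha3 by 4.32 ± 0.12 and Myh11 by 4.23 ± 0.19. Below it were Hbb-bs at -7.53 ± 1.19, Hba-a1 at -7.37 ± 1.12, Hp, the haptoglobin gene, at -5.40 ± 0.30, Enpp2 at -4.52 ± 0.19 and Cxcl13 at -4.44 ± 0.27. Without preadipocyte replicate 3, which held 7029 and 7370 CPM of Hbb-bs and Hba-a1, these were at -6.27 and -6.21, a change of over 1.5 times in fold.

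The comparison of smooth muscle libraries with the mean of the other 3 populations asks which genes mark the cells labelled smooth muscle among the sorted populations. All 25 contractile genes tested were higher in smooth muscle libraries. Myh11, the smooth muscle myosin heavy chain gene, was higher by 6.16 ± 0.17 on the log2 scale, Acta2 by 5.33 ± 0.16, Tpm2 by 4.04 ± 0.11 and Lmod1 by 4.95 ± 0.12. Pericyte markers were higher in 12 of 13 cases and lower in 1, with Rgs5 at 574 CPM and Mcam at 408 CPM in smooth muscle libraries. Eln reached 58790 CPM, against 18270 in intermediate, 4575 in progenitor and 1590 in preadipocyte libraries. Lipid genes were lower in 21 of 30 cases and higher in 1, with Adipoq at 1.45 CPM and Car3 at 13.6 CPM.

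Notch genes were higher in 10 of 12 cases, Notch3 by 2.97 ± 0.12 and Hey2 by 2.37 ± 0.15. BMP response genes were higher in 11 of 14 cases and lower in 1, Bmp4 by 1.47 ± 0.16. Wnt target genes were higher in 10 of 12 cases, Nkd1 by 2.18 ± 0.12 and Ccnd1, the cyclin D1 gene, by 1.08 ± 0.16. Itga8, an integrin gene, was at 776 CPM and Igfbp2 at 278 CPM in smooth muscle libraries, higher by 5.04 ± 0.18 and 4.93 ± 0.21. Fibroblast genes were lower in 18 of 22 cases and higher in 1, Serpinf1 changing by -2.82 ± 0.16 and Lum by -2.26 ± 0.14. Oxidative phosphorylation genes were lower in 33 of 33 cases, by a median of -0.817, and adipogenic transcription factors in 12 of 19, Ebf2 changing by -3.03 ± 0.17. Dpp4 was higher than the mean of the other 3 by 2.72 ± 0.16, but at 76.6 CPM it was not called different from progenitor libraries at 93.2 CPM (adjusted p = 0.259 by edgeR). Penk and Adh1 changed by -3.56 ± 0.21 and -4.36 ± 0.17.

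The other 3 populations differed among themselves in these lists. Fibroblast genes were lower in smooth muscle in 21 of 22 cases against progenitor and against intermediate, but higher in 10 and lower in 6 against preadipocyte. Wnt targets were higher in 11 of 12 cases against progenitor, in 6 against intermediate with 1 lower, and in 4 against preadipocyte. Notch genes were higher in 10 of 12 cases against progenitor and against preadipocyte, but in 6 against intermediate with 1 lower. For pericyte markers, 10 were higher and 1 lower against progenitor, 12 higher against preadipocyte, and 9 higher and 2 lower against intermediate. Oxidative phosphorylation genes were lower in 33 of 33 cases against preadipocyte. Against progenitor 22 were lower (median -0.395), turning to 3 higher and 1 lower with library size alone (0.0468), and against intermediate 4 were higher, or 31 with library size alone. Lipid genes were lower in 27 of 30 cases against preadipocyte. Against progenitor 4 were higher and 19 lower, or 8 and 14 with library size alone, and against intermediate 6 were higher and 9 lower, turning to 9 and 5. BMP response genes were higher in 12 of 14 cases against preadipocyte and lower in 1, in 6 against progenitor (10 with library size alone) and lower in 1, and in 3 against intermediate (10 with library size alone) and lower in 2 (1 with library size alone).

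Markers of several other cell types moved in smooth muscle libraries too. Mesothelial markers, of the cells that line body cavities, were higher in 12 of 12 cases, with Krt19 at 71.2 CPM, Krt18 at 90.1 CPM and Upk3b at 419 CPM. Schwann and neuronal markers were higher in 14 of 15 cases and lower in 1. Stmn2 was at 316 CPM, Dbh and Th, enzymes of noradrenaline synthesis, at 139 and 104 CPM, and Tubb3, a neuronal tubulin gene, at 204 CPM. Endothelial markers were higher in 10 of 17 cases and lower in 3, and the list was not called (camera adjusted p = 0.24). Receptor genes stood at 926 CPM in these libraries and at most at 255 CPM on average elsewhere. With the even background subtracted, 25 contractile, 12 pericyte, 12 mesothelial and 14 Schwann and neuronal genes were still called higher.

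By camera, contractile genes (adjusted p = 4.06e-19) and pericyte markers (1.49e-06) were called, and for each adjusted p = 0.0867 with an estimated correlation. Schwann and neuronal markers were called at 3.57e-09 (adjusted p = 0.118 with an estimated correlation). Mesothelial markers (5.66e-09), fibroblast genes (5.17e-12) and Notch genes (0.000194) were called, and for each adjusted p = 0.249 with an estimated correlation. Lipid genes were called at 1.03e-08 (adjusted p = 0.394 with an estimated correlation). Oxidative phosphorylation (1.65e-14) and Wnt targets (0.00544) were called, and for each adjusted p = 0.378 with an estimated correlation. BMP response genes (0.0101) and adipogenic factors (0.000256) were called, and for each adjusted p = 0.457 with an estimated correlation. Adjusted over the list alone, 25 contractile, 12 pericyte, 12 mesothelial and 14 Schwann and neuronal genes were higher and 33 oxidative phosphorylation and 21 lipid genes lower. In all, 12140 genes differed, 7159 higher and 4981 lower. With library size alone, which moved the median of all genes by 0.327, 9793 were higher and 2349 lower. With no low-count filter 19149 genes were called, and with a minimum of 5 CPM in 3 libraries 7611.

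Against single populations, smooth muscle libraries differed in 11525 genes from progenitor (6501 higher), in 6127 from intermediate (3346 higher) and in 14182 from preadipocyte libraries (8672 higher). Without scaling beyond library size, which moved the median of all genes by 0.441 against progenitor and 0.485 against intermediate, 9683 of 11698 genes were higher in the first case and 9321 of 10454 in the second. With no low-count filter 2533 genes were higher and 4435 lower against intermediate. On the axis from progenitor (0) to smooth muscle (1), built from 7119 genes that differed by at least 2-fold, the intermediate libraries lay at 0.444 ± 0.095 (SD, n = 3), with 82.8% of genes between the 2 ends. A simulated population with progenitor levels came out at 0.0291 ± 0.0021 on this axis.

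**Figure D3:**
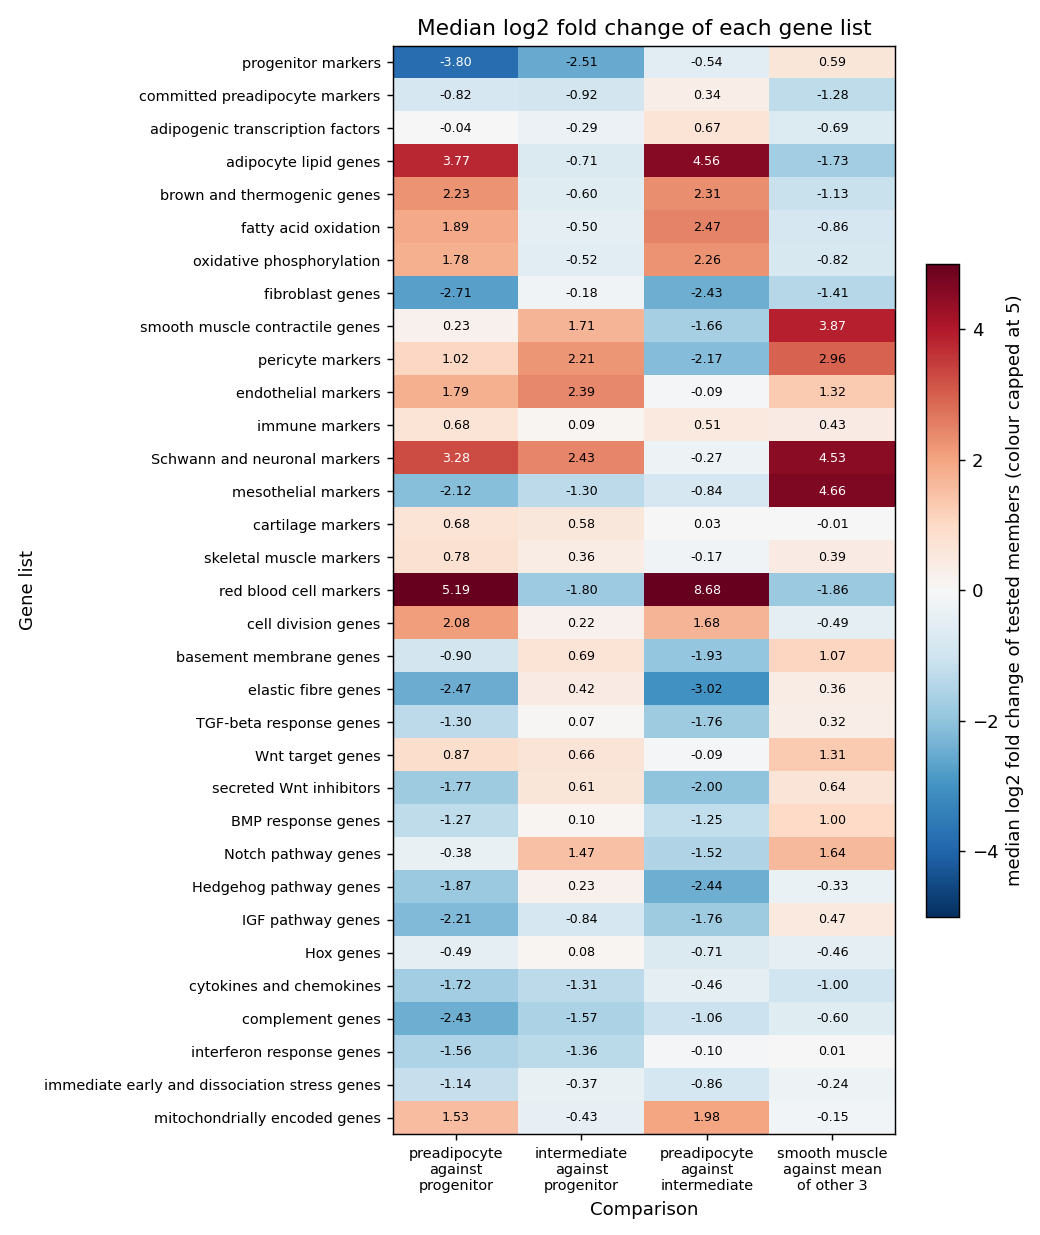
Median log2 fold change of the tested members of 33 gene lists (vertical axis) in 4 comparisons (horizontal axis), written in each cell, with red for higher and blue for lower and the colour capped at 5. Contractile genes had a median of 1.71 in intermediate against progenitor and 3.87 in smooth muscle against the other 3 populations, and adipocyte lipid genes 3.77 in preadipocyte against progenitor. The sign of 11 medians near 0 depends on the scaling, among them adipogenic transcription factors in preadipocyte against progenitor and Wnt targets, endothelial and interferon genes in preadipocyte against intermediate.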

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

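The tests on protein-coding genes alone and with an even background subtracted were chosen only after the result was seen. Except where another value is given here, each total of genes called, higher and lower together, stayed within 1.5 times its value in the report under each alternative run. Scaling with DESeq2-type size factors moved the median of all genes by 0.119 for preadipocyte against progenitor and by 0.113 against intermediate. For smooth muscle against the other 3 populations 19149 genes were called with no low-count filter and 7611 with at least 5 CPM in 3 libraries, against 12140. Against progenitor these counts were 17437 and 6948 (11525 in the report), and with at least 5 CPM 9347 against preadipocyte (14182) and 11157 for any difference (16988), where 36512 or 12659 genes were tested in place of 21285. Smooth muscle against intermediate gave 10454 with library size alone against 6127, and most of the 10454 were higher in smooth muscle, as given above. That setting differs only in leaving out the TMM factors, which were 0.823 to 0.858 in intermediate and 1.17 to 1.20 in smooth muscle libraries. Leaving out each library in turn gave 3577 (without intermediate replicate 2) to 7499 (without preadipocyte replicate 3) genes for intermediate against progenitor. No preadipocyte library enters this contrast, so the highest value can come only through the spread and scaling that the model shares. Fits and scaling on the compared libraries alone gave 7951 genes against 5870, but 9557 against 10843 for preadipocyte against progenitor. The cause of the lowest value was not tested. The fit to the compared groups alone gives no value for smooth muscle against the mean of the other 3 or for any difference.

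The position of intermediate libraries between progenitor and preadipocyte, 0.0298, was 0.0207 with DESeq2-type size factors, -0.00146 with library size alone, 0.0959 with no low-count filter, -0.0380 with at least 5 CPM, -0.00740 with no minimum fold, 0.147 with at least a 4-fold difference and -0.000523 with the background subtracted. It was 0.00255 to 0.0502 with each library left out, and the cause was not tested.

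With an estimated correlation camera called 0, 1, 0 and 0 lists in preadipocyte against progenitor, intermediate against progenitor, preadipocyte against intermediate and smooth muscle against the other 3, in place of 22, 22, 20 and 19. The fry test, which asks whether a list moves and not whether it moves apart from other genes, called 24, 21, 25 and 22 lists for one direction and 33, 30, 33 and 32 for change in either direction. Over the scalings and left-out libraries 21 to 23, 21 to 23, 19 to 21 and 17 to 21 lists were called. Calls that ended so were those of red blood cell and Hox genes given elsewhere, of basement membrane genes in smooth muscle (0.0538 without smooth muscle replicate 1, 0.0414 with all libraries) and of cell division genes in intermediate against progenitor (0.0196, and 0.111 and 0.114 without intermediate replicate 1 and progenitor replicate 3).

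Replicate numbers were tried as a block. Deviations of same-numbered libraries correlated at -0.163 to 0.207, with 6 of 18 pairs over 0.1 against 7 of 36 others. In 5 of 12 libraries the best match had the same number, so pairing stays open. The block gave 10656, 5564, 11910 and 12034 genes and 22, 23, 20 and 20 lists in the 4 main comparisons, 11383, 5941 and 14029 genes for smooth muscle against progenitor, intermediate and preadipocyte, 10352 for the midpoint, 16728 for any difference and a position of 0.0282. Under it the tests of cartilage markers in preadipocyte against progenitor (median voom value 0.0891) and of skeletal muscle markers in preadipocyte against intermediate (-0.184) turned.

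Of the named gene results, 551 to 581 kept their direction and side of the threshold under each alternative that covers all comparisons. In preadipocyte against intermediate, Dpp4 (-0.09, not called) turned to 0.0271 with DESeq2-type size factors, 0.339 with library size alone, 0.0273 in DESeq2, 0.0864 with no filter and 0.0622 with protein-coding genes, and ran from -0.418 to 0.341 with each library left out. Nkd1 turned to 0.0691 there, and mt-Co1 to 0.0182 in smooth muscle against the other 3, with library size alone. The cause was not tested.

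Among list tests, those that turned direction were uncalled both before and after, and the cause was not tested. List values here are medians of the voom log2 coefficients the tests run on, not of the edgeR fold changes given elsewhere. The signs of both differ for cartilage markers in preadipocyte against progenitor (-0.233 and 0.681), preadipocyte against intermediate (-0.308 and 0.0314) and smooth muscle (0.376 and -0.0144). A test is set against all other genes, so it can turn while the median keeps its sign. With library size alone these were immune markers in preadipocyte against intermediate (0.898) and in smooth muscle against the other 3 (0.791) and secreted Wnt inhibitors in smooth muscle (0.977). With fry they were contractile genes in preadipocyte against progenitor (0.225), immune markers (0.484) and Wnt targets (-0.138) in preadipocyte against intermediate, and cartilage markers in smooth muscle (0.376). With each library left out, these voom medians ran from 0.122 to 0.604 for contractile genes and -0.292 to 0.358 for cartilage markers in preadipocyte against progenitor, and from 0.0976 to 0.304 for Hox genes in intermediate against progenitor. In preadipocyte against intermediate they ran from -0.689 to 0.247 for endothelial, -0.0406 to 0.706 for immune and -0.342 to 0.132 for skeletal muscle markers, and from -0.236 to 0.0926 for Wnt targets. In smooth muscle they ran from 0.108 to 0.851 for immune markers, 0.116 to 0.794 for cartilage markers and 0.236 to 0.473 for elastic fibre genes. Depth limits low genes: a count of 0 allows up to 0.175 to 0.256 CPM.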

Other observations

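The tests on red blood cell precursors, on preadipocyte replicate 3, on a mixture of cells over all genes and over the fixed lists, and on genes beyond both ends of a mixture were chosen only after the result was seen, and so were the list of sympathetic neuron genes and the subtraction of an even background that other tests here use. Several signalling lists not yet described moved in preadipocyte libraries. BMP response genes were lower than in progenitor libraries in 8 of 14 cases and higher in 1 (camera adjusted p = 0.00263; adjusted p = 0.311 with an estimated correlation), and lower than in intermediate libraries in 10 of 14 (0.000945; adjusted p = 0.28 with an estimated correlation). Against progenitor, Id2, an inhibitor of transcription factors induced by BMP signals, changed by -2.25 ± 0.11 on the log2 scale and Nog, which encodes the BMP antagonist noggin, by -3.89 ± 0.29. Secreted Wnt inhibitors were lower in preadipocyte than in progenitor libraries in 6 of 9 cases and higher in 2 (0.00153; adjusted p = 0.137 with an estimated correlation), Sfrp4 changing by -4.92 ± 0.14 and Dkk3 by -4.08 ± 0.17. Frzb, another of them, was higher in intermediate than in progenitor libraries by 3.79 ± 0.23 and changed by -5.47 ± 0.26 from intermediate to preadipocyte. In smooth muscle libraries 5 of these 9 genes were higher and 3 lower, with Sfrp5 at 3.41 ± 0.29 and Dkk2 at -3.11 ± 0.16 (0.912, not called). Complement genes were lower in preadipocyte than in progenitor libraries in 8 of 12 cases and higher in 1 (0.00019; adjusted p = 0.146 with an estimated correlation), and interferon response genes in 11 of 16 with 2 higher (0.00399; adjusted p = 0.311 with an estimated correlation). Serping1, the complement C1 inhibitor gene, changed by -3.87 ± 0.14.

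Hox genes, which mark position along the body, were lower in smooth muscle than in the other populations in 8 of 21 cases and higher in 3 (adjusted p = 0.048; adjusted p = 0.653 with an estimated correlation), with Hoxc8 changing by -1.29 ± 0.19 and Hoxb1 by 2.15 ± 0.52. The call of this list ended when any 1 of 10 libraries was left out (adjusted p = 0.0538 to 0.106), all but preadipocyte replicate 3 and smooth muscle replicate 3. Against progenitor alone 10 Hox genes were lower and 2 higher, and against preadipocyte 6 lower and 4 higher, with a median of 0.0611 that turned to -0.0353 with DESeq2-type size factors. By library size alone, cell division genes summed to 1775 to 2017 CPM in smooth muscle, 1247 to 1427 CPM in intermediate and 1059 to 1269 CPM in progenitor libraries, all below preadipocyte libraries. The difference from intermediate depends on the scaling: with TMM 1 gene was higher in smooth muscle and 0 lower (median 0.0369), against 18 higher with library size alone (median 0.527). The genes of this list were tested against the other populations too. They were lower than in preadipocyte libraries in 28 of 28 cases, and against progenitor higher in 10 and lower in 1, or higher in 19 with library size alone. Against the mean of the other 3 populations, 17 were lower and 1 higher (0.00018; adjusted p = 0.634 with an estimated correlation), and 7 lower and 2 higher with library size alone. Committed preadipocyte markers were lower in intermediate than in progenitor libraries in 12 of 16 cases and higher in 3 (3.31e-06; adjusted p = 0.367 with an estimated correlation). Of the cartilage genes, Acan, the aggrecan gene, was higher in smooth muscle libraries by 5.28 ± 0.36, and the list was not called (adjusted p = 0.769). Col2a1, a collagen gene of cartilage, was at 155.9 CPM in preadipocyte replicate 1, against 5.32 and 2.51 CPM in preadipocyte replicates 2 and 3. Between preadipocyte and progenitor the cartilage list had a median of 0.681 and a mean of 1.10 by edgeR, while the test, on voom values with a median of -0.233, pointed down (0.905). Immune markers were higher in smooth muscle libraries in 5 of 17 cases and lower in 1, Coro1a by 2.70 ± 0.22, and skeletal muscle markers in 4 of 8, Myh3 by 4.25 ± 0.27 (adjusted p = 0.676 and 0.253, neither called).

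Whether chance can be excluded was asked by regrouping the libraries. In the 6 comparisons of 3 libraries with 3, fitted on those libraries alone, 1 of 10 splits, the real one, gave the most genes, and 10 splits are too few for a share under 0.05. The real splits gave 9557 genes for preadipocyte and 7951 for intermediate against progenitor, 10537 for preadipocyte against intermediate, and 12903, 8649 and 13011 for smooth muscle against progenitor, intermediate and preadipocyte, and the highest other split gave 0 genes in each by edgeR's adjusted p. At an unadjusted p under 0.05 the real splits gave 9966 to 13873 genes and the others 30 to 937, and no other tool was run on the splits. With 60 regroupings, 1 (the real one) gave as many genes as observed in each of 3 results, a share under 0.05. This shows that libraries of a population resemble each other more than those of other populations. Replicates that are technical would give the same, so differences between litters or sorts are not excluded. The real values and the highest others were 12140 and 8998 for smooth muscle against the other 3 populations, 9724 and 3891 for the midpoint contrast over 9 libraries, and 16988 and 6302 for any difference.

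Cell division genes summed to 4768, 5887 and 8662 CPM by library size alone in the preadipocyte libraries and to 1059 to 1269 CPM in progenitor libraries. The tables argue against replicate 3 alone as the source, since 28 of 28 genes were called higher without it. Precursors of red blood cells of the makeup seen in replicate 3 would give an excess in proportion to haemoglobin in the other preadipocyte replicates. Haemoglobin in these was 0.0621 and 0.07 of that in replicate 3, but their excess over progenitor was 0.48 and 0.629 of that in replicate 3. The bound set against such precursors was passed by 0.629 and missed by 0.48, so the test as set did not decide. Precursors of another makeup, and the source of the excess in replicate 3 itself, stay open. More division in the preadipocyte population itself, the difference the labels name, may also account for it and was not tested apart from these.

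Smooth muscle libraries detected the most genes and had sympathetic neuron transcripts. Library depth is argued against, since with every library thinned to the same total the lowest smooth muscle library still detected 2450 more genes than the highest other library. An even background of reads from genomic DNA may account for the detection, because by library size alone receptor genes in the lowest smooth muscle library were at 2.24 times the highest of the others. TMM scaling would lower this ratio, since the factors of these 2 libraries were 1.17 in smooth muscle replicate 3 and 0.858 in intermediate replicate 3. With these factors the ratio would fall below the bound of 2 times set for this explanation, so the bound was met only with library size alone. RNA of sympathetic neurons may account for the neuronal genes: 24 of 25 further neuron genes were called higher (24 with the background subtracted), 21 of them over 10 CPM, with Slc6a2 at 216 CPM and Gap43 at 159 CPM against 94.3 in progenitor libraries, although Uchl1 is also a fixed progenitor marker whose value had been seen. Whether a gate removed neurons is not given in the labels, and expression of these genes by the sorted cells themselves was not tested.

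Intermediate libraries lay between progenitor and smooth muscle, at 0.444 ± 0.095 of the way over all genes and at 0.398 ± 0.025 over the 1270 genes at a mean log2 CPM of at least 4. Scaling is argued against, since the lowest position with library size alone was 0.263, and so is an even background for the abundant genes, whose lowest position with it subtracted was 0.392. A mixture of cells with the levels measured in progenitor and smooth muscle libraries is argued against, because it cannot give levels beyond both. Of the genes called at 2-fold or more against progenitor, at least 14.7% over all genes and 19.5% of the abundant ones were called at 2-fold or more the same way against smooth muscle. This held under each of 3 scalings and with the background subtracted. Over all genes 169 lay above both and 274 below, or 95 and 425 with library size alone. Genes below both do not exclude a mixture if RNA of other cells raised their levels in smooth muscle libraries. The bound was 5% for genes beyond both ends together. Over all genes, those above both do not reach it by themselves with library size alone (95 of 2913). Among abundant genes those above both exceed it, with 64 of 631, or 38 of 630 with library size alone. Hhip was at 604 CPM in intermediate libraries, against 202 in progenitor and 11.91 to 14.63 in smooth muscle libraries, and the fixed lists part as well, with a median smooth muscle share of 0.119 (quartiles 0.0975 to 0.163) implied by contractile genes and one of 0.944 (0.646 to 1.07) by progenitor markers. The shares implied by genes higher and lower in smooth muscle differed by factors of 4.02, 1.91 and 1.82 over all genes. Over abundant genes the factors were 1, 1.35 and 1.58, all within the factor of 2 set beforehand as the mark of a mixture. This test on a mixture, the only 1 set beforehand, thus came out for it, while the tests that argue against it were chosen afterwards. A distinct cell state or a mixture with a further cell type may be a candidate explanation, which the design does not test.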
